A study of Mus musculus with 2 samples.

How the data were processed

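H3K27me3 was profiled by ChIP-seq in forebrain tissue of B6NCrl mouse embryos at day 11.5, in 2 biological replicates that were pools of 109 and 88 embryos, male and female together. Per the labels, each replicate had 2 technical replicates. Peaks had been called on each replicate and on the reads of both together, and a further list holds the pooled peaks kept by comparison with both replicates, per the deposited file descriptions, which name the same control alignments for both replicates. The aligner, the peak caller and their settings are not given in the sources used here, and the assembly was mm10, per the deposited file descriptions. They also give the format as narrowPeak, in which a broad stretch of the mark can be listed as several peaks, so peak numbers and widths depend on how the caller split it.

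Each peak carries the fold enrichment over control, a ratio computed by the authors. The deposited −log10 p-value of each peak, also from the authors' caller, was used to rank and filter peaks within a list, and the deposited −log10 q-value was not used further. A score deposited by the authors for each peak was not used further either. The lists hold no read counts, so depth per sample is unknown and the precision rests on the 2 replicates. The smallest deposited −log10 p was 2.02 to 2.04 across the lists, so weak peaks are included, and how many were called can depend on depth as well as on the mark.

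Everything below was computed from the 4 peak lists and, for gene positions, the GENCODE M21 annotation and genome sequence of the same assembly, with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Protein-coding genes on chromosomes 1 to 19 and X were used, 21755 in all. The 183 protein-coding genes of chromosome Y and 13 of the mitochondrion were left out, and no list had a peak on Y. A promoter was the window of 1 kb either side of the 5′ end of the gene record, and it counted as marked when a peak of the authors' replicated list overlapped it by at least 1 bp. A promoter called unmarked can still hold a peak in a replicate's own list. Among the named unmarked genes this held in both replicates at Emx2, in replicate 1 at Camk2a, Nog and Cdkn1b, and in replicate 2 at Dcx, Gap43, Gabra1, Gabrb2, Meox1, Pdgfrb, Wnt8a, Gdf5, Inhba and Aebp2. The covered share is the percent of the 5 kb either side of the start that lies in peaks. The replicated list comes from pooled reads, so its cover can exceed that of both replicates. Domains were replicated peaks merged across gaps of up to 5 kb, and wide domains were those of at least 20 kb. Promoter CpG content is the observed/expected ratio of CpG in the 0.5 kb either side of the start.

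The replicates were compared by overlap of at least 1 bp, by shared bases and by 100 random placements that left out the first 3 Mb of each chromosome. Marked promoters in each of 22 gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Forebrain regulators were compared with more posterior regulators by Fisher's exact test and by a two-sided permutation test of the mean covered share with 100000 resamples, with 95% intervals from 5000 bootstrap resamples of genes. Each of these 2 tests was adjusted over 2 comparisons. With 1 group there was no test between groups, and with 2 replicates no test between replicates.

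The groups, the 22 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took from each list up to 4 marked members with the highest covered share in the replicated list, ties in alphabetical order, and up to 3 unmarked members in alphabetical order, or all of them where the marked or the unmarked members numbered 5 or fewer. It also took the 10 widest domains with the genes that start in them, the 5 replicated peaks of highest fold with the nearest gene start, and up to 5 genes per replicate with the highest covered share among genes without a peak within 5 kb in the other. Genes named outside the rule were chosen after their values were seen, and the text says so there.

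Alternatives changed the promoter window (0.5 kb or 2.5 kb), the peak list (either replicate's own list, the pooled list, the 50% with the strongest p-values), the cover required, the gene start used, the overlap rule, the domain gap and the background of the list tests. Backgrounds were 10000 draws matched on 10 classes of promoter CpG content and 10000 circular shifts of the marks along the gene order. Each draw gave a marked count, with every gene marked independently at the share of other genes in its class. Lists were also thinned to 1 gene per 200 kb. The replicated list holds 10575 peaks that do not overlap a peak of both replicates by at least 50% of either peak, so an alternative limited to the other 24747 was added after seeing the data, as were the count of wide domains on autosomes and a background matched on promoter CpG content for gene families.

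The steps were tested on simulated data. Of 200 promoters given a planted peak, 200 were found marked among 21755 genes, and 0 genes differed from a direct search. In 200 simulations of the list test on 21755 genes, 79.8% of the lists raised 3-fold were called and 1.21% of the unchanged lists. Genes were marked there independently of each other, without differences in CpG content or shared domains. These shares therefore do not cover false calls in lists of neighbouring or CpG-rich genes. The permutation test of covered share, on 94 genes, called 97.0% of simulated differences of 20 points and 4.50% of simulations without a difference. In 5000 simulated peaks of which 60% were made to overlap, 60% were found to.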

Results

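H3K27me3, the histone mark laid down by the Polycomb complex PRC2 and found on silenced developmental genes, was mapped by ChIP-seq in mouse forebrain at embryonic day 11.5. There was 1 group of 2 biological replicates, pools of 109 and 88 embryos of both sexes of the B6NCrl strain, each with 2 technical replicates that the authors combined. Replicate 1 gave 64314 peaks over 22.5 Mb and replicate 2 gave 65351 peaks over 28.2 Mb of the mm10 genome. The authors' pooled list held 45156 peaks, and the 35322 of these that they listed as replicated covered 20.8 Mb, or 0.812% of the sequenced genome. The lists carry no read totals, so the sequencing depth behind them is unknown. The samples were whole forebrain tissue, so a peak cannot be assigned to particular cells or read as silence of the gene in all of them. No second tissue, stage or genotype was compared, and values given as mean ± SD are over the 2 replicates.

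The first question was how far the replicates marked the same places. Of the replicate 1 peaks, 32779 (51.0%) overlapped a replicate 2 peak by at least 1 bp, and 27657 (42.3%) of the replicate 2 peaks overlapped a replicate 1 peak. When the replicate 1 peaks were placed at random within their chromosomes 100 times, 1.94% overlapped on average and 2.10% at most, so the observed share was 26.2 times the mean. Sharing followed peak strength: 98.0% of the 10% of replicate 1 peaks with the strongest p-values were shared, against 29.1% of the weakest 10%, and in replicate 2 the shares were 95.2% and 20.0%. Shared replicate 2 peaks had a median width of 379 bp and unshared ones 202 bp. Of the unshared replicate 2 peaks, 24.8% lay on the X chromosome, against 13.4% of the shared ones, whereas in replicate 1 the shares were close, at 10.4% and 11.4%. In bases, the overlap made up 37.7% of all bases covered in either replicate. Requiring an overlap of at least 50% of both peaks lowered the share in replicate 1 to 20.6%.

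Fold enrichment over control, the authors' own value for each peak, was ranked within each list and compared across 24920 best-overlapping peak pairs. Spearman's rho was 0.467 across pairs, and 0.498 on the autosomes. Peaks are not independent replicates, so no p-value is given. The 5 replicated peaks of highest fold enrichment included 4 that spanned the start of a developmental or signalling gene. The strongest, at chromosome 5 from 147301725 to 147313585, spanned the start of Cdx2, a regulator of posterior body and gut identity, with a fold of 17.003. A peak at chromosome 5 from 35277091 to 35282501, over Adra2c, an adrenergic receptor gene, had a fold of 16.8. Neurog3, a regulator of pancreatic endocrine cells, and Sox18, a regulator of endothelial cells, each lay in a peak of 15.7-fold, on chromosome 10 from 62127293 to 62134788 and on chromosome 2 from 181669922 to 181673328. The remaining peak, 16.2-fold, lay on chromosome 11 from 118567508 to 118571824, with its summit 92574 bp from the nearest protein-coding start, that of Engase.

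Promoters were the class of sequence in which the mark was most concentrated. Windows of 1 kb either side of protein-coding gene starts took 16.1% of the bases of the replicated list but make up 1.60% of the genome, a 10.1-fold enrichment. In the single replicates the enrichment was 8.55-fold ± 0.142 (SD, n = 2). Exons outside promoters held 9.82% of the peak bases, 2.92 times their share of the genome. Introns held 36.3%, 1.00 times their share, and intergenic sequence 37.7%, or 0.641 times its share. These enrichments differed between the classes by more than the spread between the replicates, whose largest SD was 0.212-fold, in exons.

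The X chromosome carried more peaks per Mb than any autosome in both replicates, at 42.8 in replicate 1 and 79.7 in replicate 2, or 1.86 and 3.95 times the autosomal median. Chromosome 19 was the highest autosome in each, at 39.6 and 39.9. The X carried 7005 peaks in replicate 1 and 13037 in replicate 2, a ratio of 1.86, while the ratio on the 19 autosomes ran from 0.842 to 1.006 with a median of 0.920. In bases every autosome gained in replicate 2, by ratios of 1.13 to 1.27, and the X by 2.05. In replicate 1 the X had 10.7 kb of peaks per Mb, 1.34 times the autosomal median of 7.99 and below chromosome 19 at 15.5. In replicate 2 the X had 21.9 kb per Mb, 2.26 times the autosomal median of 9.69 and above every autosome, of which chromosome 19 was the highest at 19.3. X promoters differed less: 19.7% of 948 X genes were marked in replicate 1 and 23.4% in replicate 2, against 19.2% and 19.4% of 20807 autosomal genes. With 1 pool on each side, this difference between the replicates has no replicate check of its own. Restricted to the 50% of each list with the strongest p-values, the X reached 0.951 times the autosomal median in peak bases per Mb in replicate 1. In replicate 2 it reached 1.48 times.

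**Figure D1:**
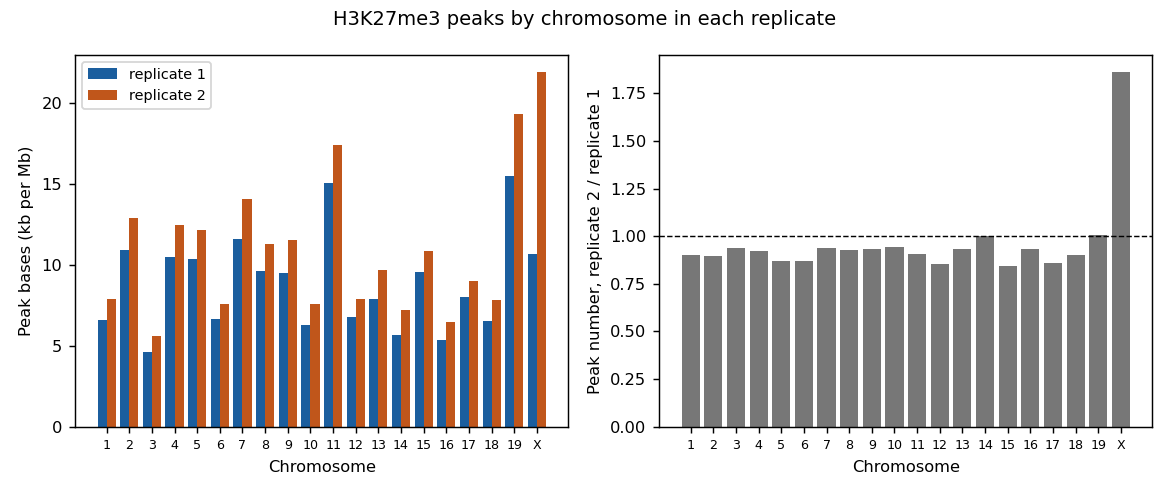
Peak bases in kb per Mb of sequenced chromosome (left, bars from 0, replicate 1 beside replicate 2) and the number of replicate 2 peaks over replicate 1 peaks (right, dashed line at 1) for chromosomes 1 to 19 and X. The autosomes lie between 0.842 and 1.006 on the right, and the X lies at 1.86.

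The mark lay on the promoter of 3414 of 21755 protein-coding genes, or 15.7% (95% Wilson interval 15.2% to 16.2%, which covers counting error only). The replicates marked 4192 and 4264 promoters, 3371 of them in common. The marked share varied with promoter CpG content. When genes were split into 10 groups by CpG observed/expected ratio, 0.966% of promoters were marked in the lowest group. The share reached 31.2% in the fifth, where the median ratio was 0.4845, and was 12.5% in the highest. Both replicates showed this order, with 35.6% and 37.4% of promoters marked in the fifth group and 15.5% and 16.4% in the highest. When a peak had to cover at least 50% of the window, 1588 promoters were marked.

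Regulators listed here for regions behind the forebrain were marked without exception. All 39 Hox genes, which pattern the hindbrain, spinal cord and trunk, had a marked promoter, as did all 20 midbrain and hindbrain regulators and all 22 spinal cord and ventral neural tube regulators. In each of these lists every promoter was also marked in both replicates. Around Hoxa4, Hoxa5, Hoxb5 and Hoxd11, replicated peaks covered 100% of the 5 kb on either side of the start, and the replicate mean was 97.9% ± 2.92 (SD, n = 2) at Hoxa4 and 99.8% ± 0.311 at Hoxb5. Gata2, an interneuron and blood regulator, was covered over 96.3% ± 2.23, Gbx2, a regulator of the midbrain-hindbrain boundary, over 91.8% ± 6.63, Lmx1b over 93.7% ± 3.75 and Pax5 over 87.0% ± 7.37. The motor neuron regulator Mnx1, with its start at chromosome 5 position 29478470, had 95.4% ± 3.86, Evx1 95.1% ± 5.92, Prdm12 92.3% ± 7.99 and Tlx1 94.1% ± 2.91. Against 15.6% of all other genes, the marked share was 6.41-fold higher in the spinal list, with an adjusted exact p of 1.40e-17, and 6.40-fold higher in the midbrain and hindbrain list, with an adjusted exact p of 4.31e-16. For Hox genes the ratio was 6.43 (adjusted exact p = 3.93e-31). These are Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over the 22 lists.

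Regulators of the forebrain itself were also mostly marked, with named exceptions. In tissue of several regions and cell types, a peak does not show that a gene was silent in the cells that use it. Of the 19 pallial regulators, which act in the future cortex, 15 were marked (5.05-fold, adjusted exact p = 3.80e-09). Among them were the proneural genes Neurog1 (chromosome 13, start at 56252163), covered over 92.2% ± 5.10 (SD, n = 2), and Neurog2, over 70.98% ± 9.26. Dmrt3 had 67.7% ± 27.5, which rested largely on replicate 2 at 87.2% against 48.3% in replicate 1, and Dmrta2 had 73.4% ± 6.70. Emx2, a regulator of cortical area identity that starts at chromosome 19 position 59458372, had no replicated peak at its promoter although both replicates had a peak there and 30.7% ± 11.2 of the surrounding 10 kb was covered, so 16 of the 19 were marked in each replicate. Otx1 (15.1% ± 2.03), Neurod6 (3.57% ± 2.72) and Dmrta1 (0% in both replicates) were unmarked in both replicates as well as the replicated list. Of 18 subpallial regulators, which act in the ganglionic eminences, 17 were marked (6.04-fold, adjusted exact p = 1.15e-12). Against draws matched on promoter CpG content the ratio fell to 3.93, still past the threshold, and with at least 50% of the window covered it was 10.7. Olig2, which starts at chromosome 16 position 91225457, was covered over 89.2% ± 6.76, Nkx2-1 (chromosome 12, 56536908) over 89.1% ± 3.45, Gsx2 over 85.5% ± 2.88 and Lhx6 over 85.1% ± 7.86, while Meis2 was the unmarked member. Of 15 diencephalic and eye regulators 13 were marked (5.54-fold, adjusted exact p = 5.27e-09), led by Vax2 at 95.4% ± 0.573, Foxb1 at 91.2% ± 6.38, Barhl2 at 85.5% ± 10.9 and Rax at 83.5% ± 9.51. The unmarked members were Hesx1 (3.16% ± 1.51) and Tcf7l2 (0.825% ± 1.17).

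Genes of dividing neural progenitors were marked no more often than other genes. Of the 20 progenitor genes 3 carried the mark, 15% against 15.7% of other genes (adjusted exact p = 1 by Fisher's test). They were Sox1 on chromosome 8 (start 12395295, 32.8% ± 4.19 covered), the Notch target Hes5 (30.6% ± 3.81) and Zic1 (33.7% ± 7.73). The adhesion gene Cdh2, the Notch ligand gene Dll1 and the radial glia gene Fabp7 were unmarked, with at most 2.85% ± 1.70 covered, at Dll1. The progenitor share differed between the replicates, at 30% and 15%, and replicate 1 alone gave a ratio of 1.56, without passing the test.

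Both lists of neuronal genes were marked more often than other genes. Of 20 early neuron genes 10 were marked (3.19-fold, adjusted exact p = 5.29e-04 from Fisher's test). These included the transcription factor gene Insm1 (54.4% ± 10.9 covered), the neurofilament gene Ina (43.7% ± 2.23), Mapt, which encodes tau (41.3% ± 6.12), and Nhlh2 (38.8% ± 9.16). Dcx, Elavl4 and Gap43 were unmarked. Of 24 synaptic and interneuron genes 15 were marked (4.00-fold, adjusted exact p = 4.48e-07). Slc32a1, the vesicular transporter of inhibitory neurons (chromosome 2, start at 158610767), was covered over 87.6% ± 8.21 and the GABA-synthesis gene Gad2 over 65.6% ± 24.5. The glutamate transporter genes Slc17a7 and Slc17a6 had 59.4% ± 3.74 and 47.0% ± 8.76. Camk2a, Gabra1 and Gabrb2 were unmarked. The median cover over each whole list was 4.25% for early neuron and 11.99% for synaptic genes in the replicated list. In replicates 1 and 2 it was 4.57% and 9.29% for early neuron genes and 9.74% and 17.9% for synaptic genes. Glial genes did not pass, at 4 of 14 (adjusted exact p = 0.298). The marked ones were Olig1 (85.6% ± 2.36), Sox8 (29.9% ± 4.67), Mbp (5.66% ± 2.22) and Cspg4 (4.69% ± 4.07), and Aldh1l1, Aqp4 and Cnp were among the unmarked. When any annotated transcript start counted, the glial list passed, at 2.33-fold. When a peak had to cover at least 50% of the window, the early neuron list no longer passed, at 2.06-fold.

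Regulators of other germ layers and tissues were marked as well. Of 25 mesoderm, muscle and heart regulators 19 were marked (4.86-fold, adjusted exact p = 8.29e-11 from Fisher's test), with 97.2% ± 2.21 covered at Foxf1, 93.4% ± 7.997 at T (Brachyury), 94.1% ± 4.11 at the heart gene Hand1 and 86.8% ± 13.3 at Tbx5. Meox1, Msgn1 and Myf5 were unmarked. Endoderm regulators were marked at 12 of 15 (5.11-fold, adjusted exact p = 1.15e-07), including Cdx2 (97.5% ± 3.49), Onecut1 (90.9% ± 3.63), Foxa2 (88.4% ± 5.72) and the pancreatic gene Pdx1 (88.9% ± 3.46), whereas Hnf1a, Hnf4a and Isx, genes of gut and liver, were unmarked. Neural crest and mesenchyme genes were marked at 20 of 25 (5.12-fold, adjusted exact p = 5.85e-12). The transcription factor genes Pitx1, Barx1, Tfap2a and Msx2 were covered over 91.5% to 93.4%, and the unmarked genes were Prrx2 and 4 that encode matrix proteins or a receptor, Col3a1, Dcn, Lum and Pdgfrb. In the list of blood, endothelial and microglial genes 10 of 22 were marked (2.90-fold, adjusted exact p = 0.00128). Tal1, a regulator of blood formation, had 88.7% ± 1.12, Sox7 71.9% ± 15.9, and the VEGF receptor genes Flt1 69.4% ± 7.20 and Kdr 46.5% ± 15.3. Aif1, Cdh5 and Csf1r, expressed in microglia or endothelium, were unmarked. Of 20 pluripotency genes 13 were marked (4.15-fold, adjusted exact p = 1.40e-06), among them Tbx3 (79.6% ± 5.32), Utf1 (56.7% ± 16.3), Prdm14 (52.8% ± 5.92) and Nodal (36.9% ± 10.6), while Dppa2, Dppa4 and Dppa5a had no peak within 5 kb in either replicate. Germline genes were marked at 1 of 19, Stag3 (2.75% ± 0.700), and did not pass (0.335-fold, adjusted exact p = 0.377; 0.819-fold in replicate 1 alone, where 15.8% were marked, and 0.268-fold in replicate 2 alone), with Brdt, Dazl and Ddx4 free of peaks.

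Genes of secreted signals were marked often as well. Wnt ligands carried the mark at 17 of 19 promoters (5.73-fold, adjusted exact p = 7.01e-12 from Fisher's test), with Wnt10b at 92.0% ± 5.41, Wnt10a at 89.95% ± 11.7, Wnt1 at 85.5% ± 7.37 and Wnt3 at 84.4% ± 7.45 of the 10 kb covered. Wnt5b and Wnt8a were the unmarked members. In the BMP, hedgehog and FGF list, which holds the BMP antagonists too, 21 of 25 were marked (5.38-fold, adjusted exact p = 3.57e-13). Fgf8, a patterning signal of the anterior neural ridge and the midbrain-hindbrain boundary, had 91.3% ± 3.58, Gdf7 85.3% ± 6.32, Shh, the ventral patterning signal with its start at chromosome 5 position 28467256, 73.2% ± 4.68 and Bmp7 70.2% ± 13.0. Bmp5, Gdf5, Inhba and Nog were unmarked. Among the 7 cyclin-dependent kinase inhibitors, the senescence-linked neighbours Cdkn2a (86.4% ± 3.34) and Cdkn2b (52.9% ± 6.38), which share a 43.4 kb domain on chromosome 4, and the imprinted gene Cdkn1c (39.8% ± 3.63) were marked. The promoters of Cdkn1a, Cdkn1b, Cdkn2c and Cdkn2d were not, although 23.3% ± 4.60 of the 10 kb was covered at Cdkn1a and 19.3% ± 1.39 at Cdkn2c. That list did not pass (adjusted exact p = 0.107), but did so in the replicate 1 list alone, at a ratio of 2.97, and in windows of 2.5 kb, at 3.79.

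The Polycomb and housekeeping lists did not pass the test, and olfactory receptors were marked less often than other genes. Of the 23 Polycomb and H3K27 demethylase genes 6 were marked (adjusted exact p = 0.195 by Fisher's test), with Cbx8 (71.5% ± 6.9997) and Cbx4 (70.96% ± 2.52), which lie close together on chromosome 11, ahead of Bmi1 (28.5% ± 8.69) and Phf19 (15.9% ± 8.63). Aebp2, Cbx7 and Eed were unmarked. Housekeeping genes were marked at 2 of 26, Reep5 and Pgk1, each covered over at most 5.86% ± 3.31 of the 10 kb, and did not pass (adjusted exact p = 0.436). Actb, Atp5b and B2m had no peak within 5 kb. None of the 1093 olfactory receptor promoters was marked in the replicated list, against 16.5% of other genes (adjusted exact p = 1.44e-82), Olfr1, Olfr10 and Olfr1000 among them, and 0.503% ± 0.323 (SD, n = 2) were marked in the single replicates. These promoters are poor in CpG. Of the 1135 genes with the stem Olfr, only 33.3 marked ones were expected from other genes of like CpG content (adjusted exact p = 2.57e-13). With 1 gene per 200 kb the adjusted exact p of the list was 6.96e-13. How reads that match several receptor genes were handled is unknown, so absence of a peak need not mean absence of the mark. Across the 22 lists 15 were marked more often than other genes, 1 less often, and 6 did not pass. Against draws matched on promoter CpG content the same numbers passed, but most ratios above 1 were smaller. They were 4.37 for Hox, 4.58 for spinal, 4.54 for midbrain and hindbrain, 3.87 for diencephalic and eye and 3.799 for pallial genes. The 15 ranged from 2.87 for synaptic genes to 4.65 for neural crest genes. Those of early neuron (3.41) and blood genes (3.27) were larger than against all other genes. Genes of a list can share a domain with their neighbours, so the p-values describe marks in this tissue and not independent events.

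**Figure D2:**
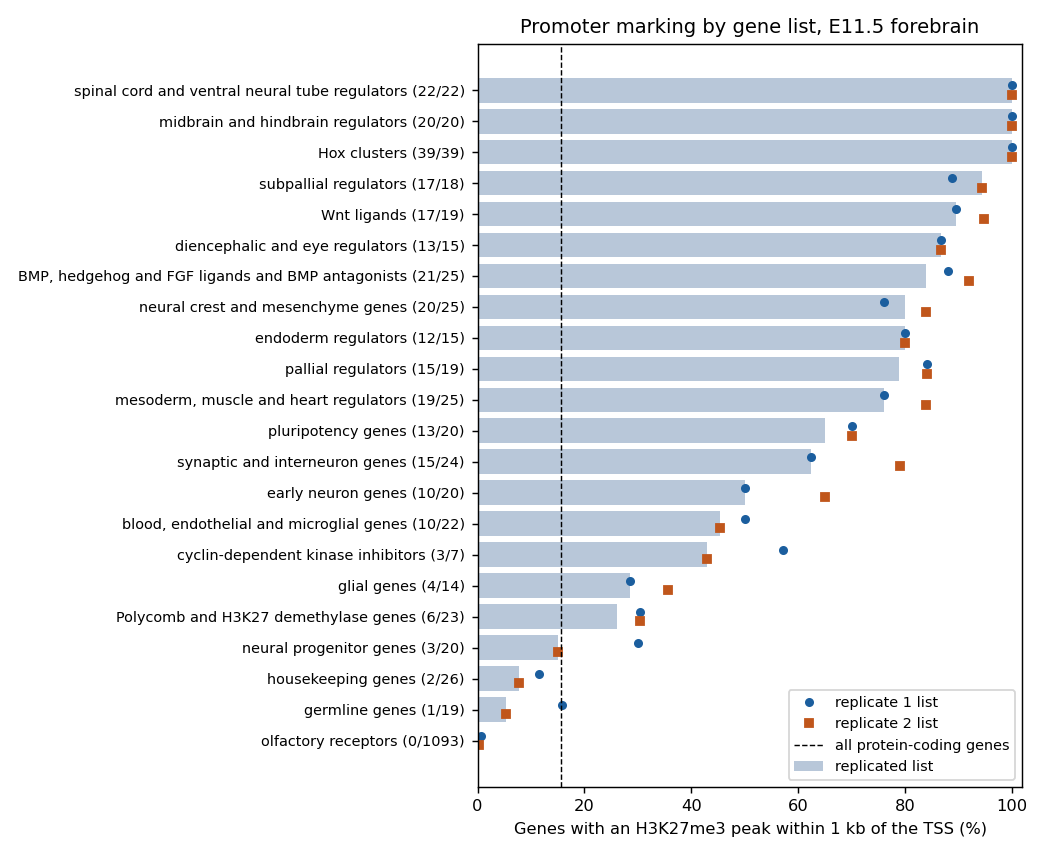
Percent of genes in each fixed list with a peak within 1 kb of the start, with marked and total genes in brackets. Bars show the authors' replicated list, circles replicate 1, squares replicate 2, and the dashed line the 15.7% of all protein-coding genes; 3 lists reach 100% in every list of peaks and olfactory receptors lie at 0% in the replicated list.

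Forebrain regulators were compared with regulators listed for more posterior parts of the neural tube. The lists do not separate the regions fully. Fgf8 of the midbrain and hindbrain list, for example, is also a signal of the anterior neural ridge. The other members on either side were not checked for use in both regions. Which of these genes were active in the sampled tissue was not measured. Of the 52 pallial, subpallial, diencephalic and eye regulators 45 had a marked promoter, against 42 of 42 midbrain, hindbrain and spinal regulators (Fisher's exact test, two-sided, adjusted p = 0.0184) and 39 of 39 Hox genes (adjusted exact p = 0.0184). The covered share, averaged over all genes whether marked or not, differed as well. The unmarked genes were all forebrain regulators, with at most 29.8% covered by replicated peaks, at Emx2, and so lowered the forebrain mean. Marked genes alone were not compared, so the difference mixes absence of the mark with its width. Replicated peaks covered on average 60.2% of the 10 kb around the starts of forebrain regulators and 81.8% around those of the midbrain, hindbrain and spinal regulators, a difference of -21.6 percentage points (95% bootstrap interval -31.4 to -12.1, permutation test p = 6.0e-05, adjusted 6.0e-05). The difference was -20.6 ± 1.95 (SD, n = 2) in the replicates and so was larger than their spread. Hox genes were covered over 96.4%, and forebrain regulators differed from them by -36.2 points (interval -45.1 to -27.9, permutation p = 2.0e-05, the smallest these permutations can give). The median cover was 54.7% for pallial, 77.9% for diencephalic and eye, 83.5% for subpallial, 87.7% for midbrain and hindbrain, 90.5% for spinal and 97.8% for Hox genes. In replicate 1 alone the pallial median was 40.9%, and in replicate 2 alone it was 57.4%. The difference in marked promoters did not pass the test in windows of 2.5 kb, at -7.69 points, or when any annotated transcript start counted, at -3.85 points. Against Hox genes it did not pass with 1 gene per 200 kb either, at -14 points (exact p = 1), since the Hox genes lie in 4 clusters and few are left.

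**Figure D3:**
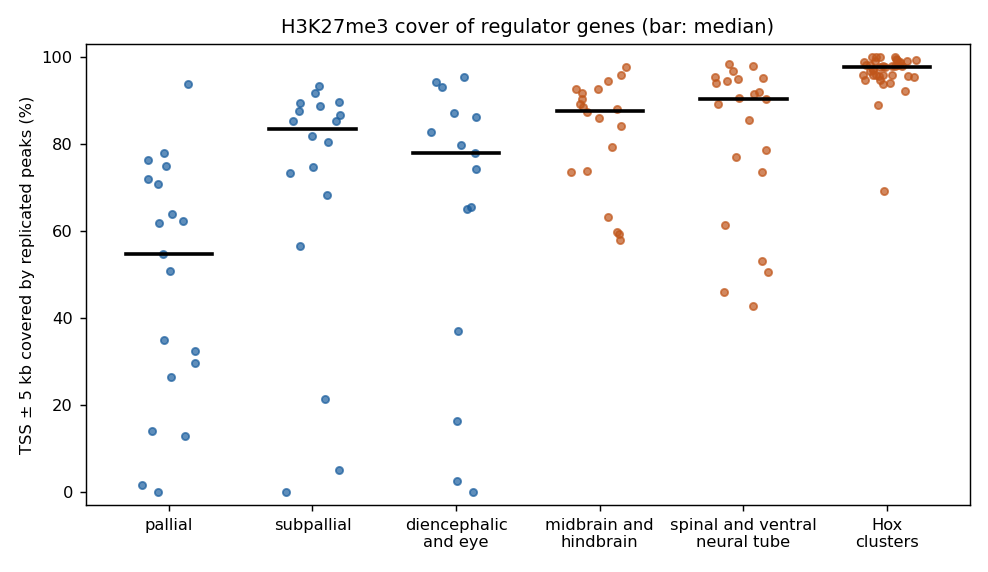
Percent of the 10 kb around each gene's start covered by replicated peaks, with 1 point per gene and a bar at the median of each list, forebrain lists in blue and more posterior lists in orange. Pallial genes spread from 0% to 93.8% around a median of 54.7%, and Hox genes lie around 97.8%.

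Merging replicated peaks across gaps of up to 5 kb gave 9190 domains with a median width of 1.89 kb. Of these, 355 were at least 20 kb wide and held the starts of 279 protein-coding genes. All 4 Hox clusters were among the 10 widest. HoxA with Evx1 lay in a domain of 181.0 kb on chromosome 6 (52146130 to 52327127), covered by peaks over 85.0% ± 4.22 (SD, n = 2). HoxC spanned 170.6 kb on chromosome 15 (102904930 to 103075520), at 90.3% ± 3.86, and HoxB 133 kb on chromosome 11 (96245820 to 96378769), at 91.5% ± 2.59. HoxD with Evx2 took up 126 kb on chromosome 2 (74643560 to 74769753), at 88.9% ± 4.72. The other 6 lay on the X chromosome, were 96.1 kb to 176 kb wide and were filled less densely. The widest of them, at X 103673880 to 103849873 with the start of the thyroid hormone transporter gene Slc16a2, was covered over 29.8% in replicate 1 and 51.7% in replicate 2. Those at X 152112329 to 152228237, 94302465 to 94401830 and 94087930 to 94184027 held the starts of Iqsec2, of Fam90a1b and Apoo, and of Zfx, and those at X 99483439 to 99612957 and 167634093 to 167738489 held no protein-coding start.

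Starts in domains of at least 20 kb were more frequent than among other genes in every regulator list and in some other lists. All 39 Hox genes lay in such domains, against 1.11% of other genes (Fisher's exact test, adjusted p = 2.29e-74 over the 22 lists). So did 16 of 22 spinal (adjusted exact p = 2.66e-25), 13 of 20 midbrain and hindbrain (1.01e-19), 11 of 18 subpallial, 10 of 15 diencephalic and eye, 10 of 25 neural crest, 8 of 25 mesoderm, 5 of 15 endoderm (1.99e-06) and 7 of 19 pallial genes (5.71e-09). Wnt ligands matched the pallial list, at 7 of 19 (29.4-fold, adjusted exact p = 5.71e-09). Kinase inhibitors passed at 2 of 7 (22.4-fold, 0.00605), with Cdkn2a and Cdkn2b in a shared domain, and progenitor genes at 2 of 20 (7.85-fold, 0.0453), Sox1 and Zic1. Polycomb genes (2 of 23, 0.0546) and the BMP, hedgehog and FGF list (2 of 25, 0.0594) did not pass, nor did the synaptic, glial and pluripotency lists with 1 gene each. None of the early neuron, blood, germline or housekeeping genes did, and none of these 4 lists passed. No olfactory receptor did either, fewer than among other genes (adjusted exact p = 2.26e-06). These tests count each gene although neighbours share a domain, and the lists were not thinned for them. Most Hox genes lay in 4 domains, and those of HoxA and HoxD also held Evx1 and Evx2 of the spinal list. Wnt1 and Wnt10b shared a domain as well. The p-values therefore describe marks in this tissue and not independent events. Autosomal domains of at least 20 kb numbered 275, of which 60.7% held a protein-coding start and a median of 63.0% of the bases was covered by peaks. On X there were 80, of which 23.8% held a start, with a median of 19.8% covered. The number of wide domains was 621 in the replicate 2 list and 497 in the replicate 1 list, and 110 when gaps of only 1 kb were bridged.

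**Figure D4:**
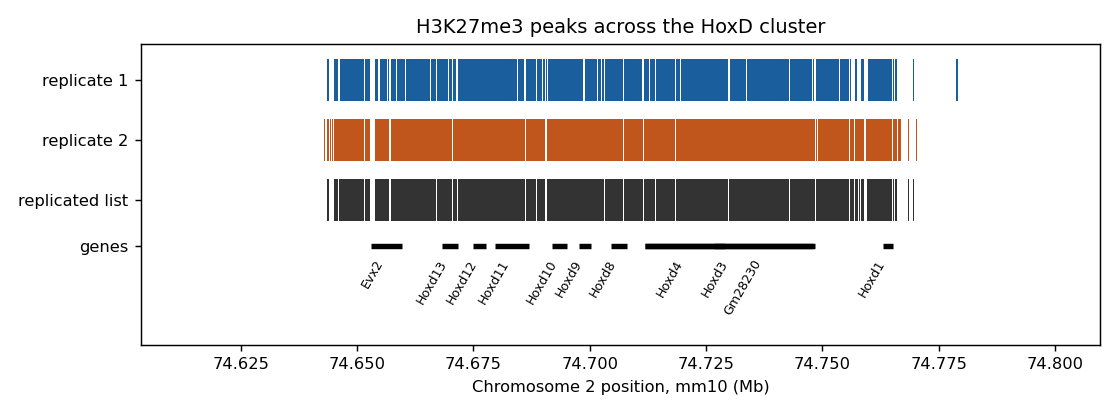
Peaks of replicate 1, replicate 2 and the replicated list across the HoxD cluster on chromosome 2 in mm10 coordinates (Mb), with protein-coding genes as black bars. Peaks cover most of the domain from Evx2 to Hoxd1 in both replicates, and the flanks of 40 kb on either side are almost empty.

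Genes with peaks in a single replicate had little of their surroundings covered. Replicate 1 alone had peaks within 5 kb of 1773 gene starts, with at most 9.65% of the 10 kb covered, at Arhgef10, followed by Tmem52, 1700086D15Rik, Arhgap44 and Igsf3 (8.59%). Replicate 2 alone did so at 1113 starts, led by Mgat4a at 19.04%, Kctd12 at 17.3%, the X-linked Armcx3 at 16.0%, Maf, a transcription factor gene, at 15.9% and the X-linked S100g at 15.7%. Of these genes 44 lay on X in replicate 1 and 69 in replicate 2.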

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

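Limiting the list to peaks found in both replicates, counting wide domains on autosomes, and matching families on promoter CpG content were alternatives chosen after seeing the data. Of 264 list results under 12 alternatives, 254 kept direction and side of the threshold, including every one for the 5 neural tube lists and Hox genes. Progenitor genes never passed but had a ratio above 1 with peaks in both replicates (1.07), windows of 2.5 kb (1.06) and 0.5 kb (1.19), and from 0.765 to 1.56 with either replicate left out. Kinase inhibitors passed in windows of 2.5 kb (3.79), with any transcript start (3.88) and in replicate 1 alone (2.19 to 2.97 with either replicate left out), and glial genes with any transcript start (2.33). With at least 50% of the window covered, early neuron genes missed the threshold (2.06), the Polycomb list had a ratio of 0, and 1588 promoters were marked. The forebrain difference in marked share missed it against both posterior and Hox genes in windows of 2.5 kb (-7.69) and with any transcript start (-3.85), and against Hox genes with 1 gene per 200 kb (-14), which leaves few Hox genes. The difference in covered share passed under every alternative run. Overlap in replicate 1 was 20.6% at 50% of both peaks, 44.7% at 50% of either, 58.4% for the stronger 50% of each list and 34.7% after merging, and rho was 0.558 for pairs overlapping by 50%. Promoter enrichment was 8.45 to 8.65 with either replicate left out, 9.66 in the pooled list, 11.1 in the stronger 50%, 10.7 for peaks in both replicates, 7.82 by midpoints and 7.74 by summits. On X, replicate 2 stood at 2.26 times the autosomal median in peak bases per Mb and at 1.48 in the bases of its stronger 50%. In peaks per Mb, over its whole list, it stood at 3.95. Wide domains numbered 110 with gaps of 1 kb, 571 with 10 kb, and 497 to 621 with either replicate left out. Median cover within 10 kb of the start was 37.4% for pallial, 66.9% for subpallial, 64.2% for diencephalic and eye, 72.7% for midbrain and hindbrain and 79.0% for spinal genes, and within 2.5 kb 86.0% for diencephalic and eye genes. With either replicate left out the medians ran from 94.3% to 97.8% for Hox, 40.9% to 57.4% for pallial, 73.8% to 84.8% for subpallial, 70.0% to 79.3% for diencephalic and eye, 80.3% to 87.8% for midbrain and hindbrain and 85.2% to 90.2% for spinal genes. Families marked more often numbered 15, not 24, when matched on promoter CpG content. The cause of these changes was not tested. Unknown depth limits what the absence of a peak can mean.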

Other observations

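The tests of X peaks across all chromosomes and of the ribosomal RNA gene, the comparison of single forebrain lists, and the families below were chosen only after the data were seen. Of the forebrain lists, the pallial list had the lowest cover. Its 19 genes were covered over 48.0% on average, a difference of -33.8 points from the 42 midbrain, hindbrain and spinal genes (permutation test, adjusted p = 1.2e-04 over 6 tests), and the difference was -32.3 ± 4.21 (SD, n = 2) in the replicates. The diencephalic and eye list differed by -17.9 points (permutation test, adjusted p = 0.0433), and the subpallial list by -11.8, which did not pass (permutation test, adjusted p = 0.0920). The pallial list did not pass against the other forebrain genes (-19.2 points, permutation test, adjusted p = 0.0680). Among genes named here after their values were seen, Foxg1, a regulator of telencephalic identity, was covered over 31.3% ± 16.2, Lhx2 39.4% ± 20.3 and Ascl1 20.4% ± 10.4, against 83.8% ± 8.94 at Dlx1 and 80.5% ± 10.9 at Six3. Pax6 and Eomes, which mark dorsal progenitors and their progeny, had 64.3% ± 11.2 and 70.1% ± 7.03.

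Genes grouped by symbol stem gave 211 families of at least 12 genes, of which 24 were marked more often than other genes and 15 less often (Fisher's exact test, adjusted over the families). Among families with few or no members in the fixed lists, serotonin receptor genes (Htr) were marked at 11 of 14 (5.02-fold, adjusted exact p = 1.13e-05) and voltage-gated calcium channel genes (Cacna) at 9 of 14 (4.105-fold, adjusted p = 0.00103). Collagen genes (Col) were marked at 21 of 45 (2.99-fold, adjusted exact p = 2.94e-05) and synaptotagmins (Syt) at 11 of 17 (4.13-fold, adjusted p = 1.81e-04). Zinc finger genes with the stem Zfp were marked at 21 of 394 (0.336-fold, adjusted exact p = 7.83e-09). No promoter was marked among 67 genes with the stem Hist, most of which encode histones (adjusted exact p = 5.13e-04), 331 vomeronasal receptor genes (Vmn, adjusted p = 3.49e-23) or 49 mitochondrial ribosomal protein genes (Mrpl, adjusted p = 0.00503). Against other genes matched on 10 classes of promoter CpG content 15 families passed as higher and 11 as lower (exact test, adjusted over the families), 15 and 9 of them as above. The named families were among these, with ratios of 3.93 for Htr, 4.90 for Cacna, 2.48 for Col, 2.86 for Syt and 0.249 for Zfp. Vomeronasal receptor promoters are poor in CpG, and only 7.24 marked ones were expected after matching (adjusted exact p = 0.0154), against 10.8 for Hist and 10.5 for Mrpl (adjusted exact p = 3.42e-04 for each). Neighbouring members of a family can share a domain. The aligner's settings are not given, so the handling of reads that match several members of a family is unknown. Absence of a peak there need not mean absence of the mark.

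Replicate 2 had 1.86 times the X peaks of replicate 1. Higher sensitivity on every chromosome would give autosomes a like gain. Their highest ratio was 1.006 in peak numbers. They did gain in bases, by 1.13 to 1.27 against 2.05 on X, and among peaks with a −log10 p of at least 8, by 1.28 to 1.95 against 3.38. The X lay above every autosome in each measure, which argues against an equal gain as the whole cause, while an effect of sensitivity that differs between X and autosomes stays open, since depth is unknown. A few places on X would leave most bins alone, but 95.5% of the 22 bins of 5 Mb with at least 20 peaks over both replicates together lay above 1.006, the highest autosomal ratio. The exception was thinly filled, with 21 peaks in replicate 1 and 15 in replicate 2. The value of 1.006 is a whole-chromosome ratio, and autosomes were not split into bins, so the scatter of autosomal bins is unknown. The median ratio of the X bins was 1.81. Weak peaks alone would lose the excess at a −log10 p of at least 8, but there the X ratio was still 2.40 times the autosomal median ratio. That cut kept 240 of the 7005 X peaks of replicate 1 and 810 of the 13037 of replicate 2. The excess was thus not confined to weak peaks, but most of the added X peaks were weaker than the cut. The autosomal median ratio rose from 0.920 over all peaks to 1.41 at this cut, so an effect of the calling threshold on those weaker peaks stays open. A larger number of inactive X chromosomes, for example from more female embryos in the second pool, may account for it, but the genes Kdm5c, Kdm6a, Ddx3x, Eif2s3x, Pbdc1 and Utp14a, chosen as known to escape inactivation, could not decide (permutation p = 0.953), since 5 of the 6 had no peak in their bodies in either replicate. The sex ratio of the pools is not known here, and X dosage relative to the shared control stays open with it.

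The lower cover of forebrain regulators, unmarked genes included, kept its size in 3 alternative settings. The difference of -21.6 points from midbrain, hindbrain and spinal regulators was -22.6 after removing the linear trend on promoter CpG content. It was -22.3 with each gene's widest-covered transcript start, and -21.5 with 1 gene per 200 kb. These values argue against the choice of gene start and repeated neighbours as the whole cause, and against a linear effect of promoter CpG content. The marked share of all genes reached 31.2% in the fifth CpG group but was 12.5% in the highest, so a non-linear effect of CpG content stays open. None of the 3 settings separates absence of the mark from its width. No biological explanation was tested, since the series holds 1 tissue and no expression values were used here.

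The replicated list held 4 peaks with a −log10 p of at least 50, and 2 of them had folds of 3.02 and 2.97, where the other 2 had at least 16.8. They lay on chromosome 17 from 39843035 to 39846771 and from 39847737 to 39848900. Reads from the many unassembled copies of ribosomal RNA genes may explain them, since 100% of the 2 overlapped the ribosomal RNA gene annotated there. The overlap takes in 11.2% of the bases of the first peak and 93.7% of the second, so it rests on 2 peaks of unequal overlap, and the control reads at this place were not used here.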
